A study of Rattus norvegicus with 14 samples.

How the data were processed

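Total liver RNA of 14 rats (7 per group) was converted to biotin-labelled sense-strand DNA and hybridised with a whole-transcript Affymetrix protocol, 1 array per rat, per the labels' protocols. The deposited values are log2 expression values, 1 column per rat and 29215 rows (transcript clusters, called probes here). Per the submitters' processing notes, RMA and Affymetrix Expression Console 1.1.2 were used. RMA as a method corrects background, quantile-normalizes the arrays and summarises the probes of a transcript cluster by median polish; which options the authors set is not given in the sources used here, nor is a genome build. The log2 scale of the deposited values was read from their range, 1.95 to 14.0 over the 14 arrays. RMA compresses folds near background, and no detection calls were used, so folds of genes that are dim in a group may be too small. Array medians over all probes still differed slightly (5.02 to 5.15). The sample labels give the extract dose as 0.05% of the diet by weight, whereas the series title gives 0.5%; the dose of the sample labels is printed. Groups and rat numbers were taken from the sample titles. No batch or scan date was used here.

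Probes were named through GEO's platform annotation, which lists 15633 of the probes: 15310 with exactly 1 gene symbol and 323 with several, leaving 13582 unnamed here. Symbols were updated through the Entrez identifier against NCBI's gene table of the GRCr8 assembly, which held 15279 of the 15310 identifiers and changed 0 symbols. For the 527 genes with more than 1 probe, the probe with the highest mean over the 14 arrays was used, giving 14506 genes. Of the 457 genes called, 14 had more than 1 probe: in 0 of them did another probe have the opposite sign, and in 12 every other probe moved the same way at an unadjusted p under 0.05. All values were used as deposited, with no filter on dim probes.

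The 2 groups were compared gene by gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate, and p-values were Benjamini-Hochberg adjusted over the 14506 genes at a threshold of 0.05. Folds are extract minus control, errors of folds are limma's standard errors, and group values are means ± SD over 7 rats. In total 29 gene lists were fixed before the data were examined, with 697 entries, of which 620 were measured; unmatched symbols were not analysed here. They cover NRF2, AHR, CAR and PXR targets, antioxidant enzymes, lipid, bile acid and glucose metabolism, inflammation, stress responses, cell cycle, respiration, clock, sex-biased genes, and markers of cell types that liver or adjacent tissue holds. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with the correlation estimated from the data and with fry. The design, the alternatives and the rule for naming genes were also fixed before the data were examined. The rule names the 6 largest rises and 6 largest falls among genes that passed (passing over loci with no proper name), up to 4 passing members of each list by smallest p (or the member with the smallest p where none passed), and the 3 members with the smallest p of each list camera called, 73 genes in all. The mean of a list's members per array was compared between groups by an exact permutation test over the 3432 assignments of 7 of 14 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

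The test was run on simulated data with the means of the 14506 genes and 200 changed genes per run, in 5 runs. Noise was normal, independent between genes and equal in both groups, with limma's moderated variance of each gene. The test recovered 86.6% of genes changed by 0.5 on the log2 scale, 99.7% of those changed by 1 and 100% of those changed by 2, with 5.26% false calls among all calls. Real genes correlate and can differ in spread between groups, so these rates may be too favourable. Camera at the preset correlation found the changed list in 5 of 5 runs and called 1 of 140 unchanged lists, in simulated genes that are independent, which real genes are not.

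Alternatives were repeated quantile normalization, median centring, 2 filters on dim genes (mean of at least 6, or of at least the median gene), the mean of all probes of a gene, every probe of the table, an intensity trend with robust variance, array weights, an unequal-variance test per gene, the rat number as a replicate block, an adjusted p of 0.1, camera with estimated correlation, fry, and leaving out each array in turn. The unequal-variance test uses each gene's own SDs, without limma's moderated variance. A call lost in it can come from that loss of moderation and is not by itself a sign of unequal spread. After the data had been seen, fits without the 2 arrays of lowest weight and with the largest principal component of the genes outside the lists as a covariate were added. The latter replaced a fit with the largest component within groups, which was run first and is set aside because a covariate without any group difference cannot move a fold. The component used in its place correlates at only 0.06 with the groups, so it too can hardly move a fold and acts on the residual spread. Same-numbered rats of the groups are different animals, and nothing in the labels pairs them.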

Results

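Liver gene expression was measured in 14 lean (fa/+) female Zucker rats, which carry the fa mutation of the leptin receptor gene in heterozygous form and do not become obese. After 64 days, 7 rats fed a standard diet (control) were compared with 7 rats fed the same diet with a rosemary extract added at 0.05% by weight, of which 40% was carnosic acid, a phenolic diterpene. One array was hybridised per rat, so each array is a separate animal. The values are log2 RMA values on 29215 probes, of which 14506 genes were tested. The median over genes lay between 6.00 and 6.18 in the 14 arrays, and pairs of arrays correlated between 0.984 and 0.997 across genes. The number of arrays limits the precision: the median standard error of a log2 fold was 0.087. The comparison asks which liver transcripts differ with the extract at the end of the feeding period.

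The extract was accompanied by a broad change in liver transcripts, led by enzymes that handle foreign compounds. In limma's moderated test, 457 of 14506 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 290 were higher and 167 lower with the extract. Of these, 33 rose and 7 fell by at least 1 on the log2 scale, and the median size over all 457 was 0.47. The largest rise was that of Akr1b8, an aldo-keto reductase, which went from 6.19 ± 0.88 (SD, n = 7) to 10.76 ± 0.22 (SD, n = 7), or 23.8-fold (log2 fold 4.57 ± 0.29 SE, adjusted p = 2.71e-08). Cyp2b2, a phenobarbital-inducible cytochrome P450, rose 18.9-fold, from 5.33 ± 0.38 to 9.56 ± 0.52 (SD, n = 7 each; log2 fold 4.24 ± 0.21 SE, adjusted p = 1.47e-09). Akr1b10, another aldo-keto reductase, rose 5.93-fold. Nr1i3, which encodes the nuclear receptor CAR, rose 5.20-fold from 5.08 ± 0.11 to 7.45 ± 0.38 (SD, n = 7 each; adjusted p = 6.37e-09). Its control mean lay just below 5.10, the median of all probes in controls, and signal near background can make a fold too small. The control mean of Cyp2b2 lay near that median too. Gstp1, a glutathione transferase, rose 5.15-fold and Akr7a3, an aldehyde reductase, 4.61-fold. In each of these 6 genes all 7 extract rats lay above all 7 control rats.

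The falls were smaller. Prom1, a membrane glycoprotein used as a marker of progenitor cells, fell from 8.36 ± 0.38 to 6.14 ± 0.56 (SD, n = 7 each), a log2 fold of -2.22 ± 0.22 (SE, adjusted p = 6.16e-06), with all 7 extract rats below all controls. Slc34a2, a sodium-phosphate cotransporter, had a log2 fold of -1.74, Wfdc21 of -1.58 and Cyfip2, a member of the WAVE actin-regulatory complex, of -1.57, each also without overlap between the groups. The extract means of Slc34a2 (5.35) and Cyfip2 (5.54) lay near 5.10, the median of all probes in controls, so these falls may be too small. Nrep had a log2 fold of -1.39 and Ky of -1.06, with 5 of 7 extract rats below all controls in both; the call of Ky was lost in the unequal-variance test per gene (adjusted p = 0.095). Over all genes, 224 (1.54%) showed no overlap between the groups, where chance gives 0.0583% for 7 against 7, and 208 of them were among the 457. At an unadjusted p under 0.05 there were 2154 genes, where 725 would be expected with no difference. Centring each array on its median moved the share of higher genes among the calls from 63.5% to 74.2%. Without control rat 1, 292 genes were lower in place of 167.

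**Figure D1:**
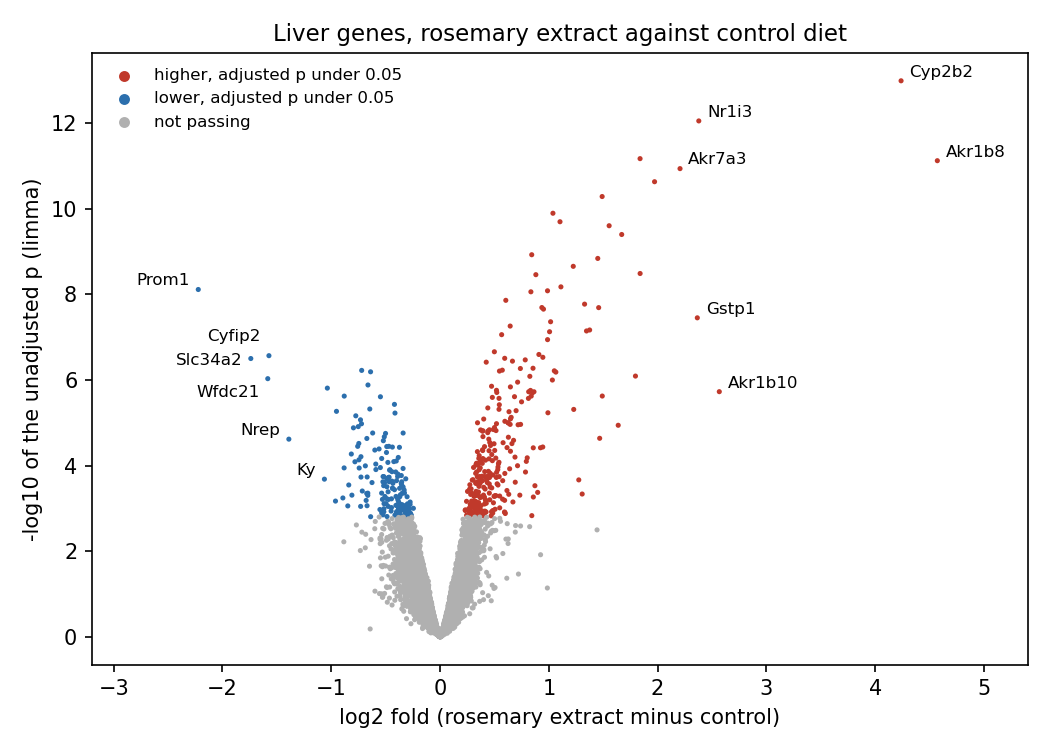
Each point is 1 of 14506 genes; the x axis is the log2 fold, extract minus control, and the y axis the -log10 of limma's unadjusted p. Red points (290) and blue points (167) passed an adjusted p of 0.05; the 12 genes with the largest rises and falls are named, with Akr1b8 and Cyp2b2 far to the right and Prom1 farthest to the left.

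Targets of NRF2, the transcription factor of the electrophile and oxidant response, rose as a group. Of 27 measured members of this list, which was fixed before the data were examined, 18 rose, 0 fell and 9 did not pass (22 rose adjusted over the list alone; 16 genes passed in the unequal-variance test per gene), with a median log2 fold of 0.84. The members with the smallest p were Akr1b8 and Akr7a3, then Abcc3, an exporter of conjugates, which rose 3.92-fold, and Nqo1, a quinone reductase, which rose 2.94-fold from 8.15 ± 0.29 to 9.70 ± 0.21 (SD, n = 7 each; adjusted p = 3.59e-07). Chosen after their values were seen, Gclc and Gclm, the subunits of the enzyme that limits glutathione synthesis, had log2 folds of 0.88 and 1.01, while Hmox1, heme oxygenase, did not pass (log2 fold -0.17, adjusted p = 0.50) and neither did the ferritin genes Fth1 (0.04) and Ftl1 (0.09). limma's camera placed the list above other genes (adjusted p = 6.05e-38 at a preset correlation of 0.01; adjusted p = 0.000286 with an estimated correlation).

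Targets of the xenobiotic receptors CAR and PXR rose as well: 14 of 23 measured members rose, 0 fell and 9 did not pass (17 rose adjusted over the list alone), with a median log2 fold of 0.51. In the unequal-variance test per gene only 8 of the 14 passed. Beside Cyp2b2, these included Aldh1a1, a retinaldehyde dehydrogenase (2.73-fold), Abcb1a, the drug exporter P-glycoprotein (2.16-fold), and Ces2c, a carboxylesterase (1.93-fold), each higher in all 7 extract rats than in any control. Camera gave an adjusted p of 1.41e-20, and adjusted p = 0.00582 with an estimated correlation. NRF2 targets and this list were the only 2 of 29 lists that camera called under both correlations. Several members belong to families of close paralogues (Cyp2b, Akr1b, Gst, Ces), and how far the array's probes separate the copies was not tested.

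Among targets of AHR, the receptor for aryl hydrocarbons, 2 of 6 measured genes rose (2 adjusted over the list alone): Nqo1, which the NRF2 list also holds, and Cyp1a1, from 3.84 ± 0.11 to 4.15 ± 0.14 (SD, n = 7 each; log2 fold 0.31, adjusted p = 0.024). Both Cyp1a1 means lay below 5.10, the median of all probes in controls and its call was lost without control rat 3 or 5 or extract rat 2 or 5 (adjusted p = 0.056, 0.053, 0.055 and 0.052). Cyp1a2, the abundant hepatic member of the family, had a log2 fold of 0.12 (adjusted p = 0.51). Camera called the AHR list upward (adjusted p = 0.00492, median 0.12), with adjusted p = 0.073 with an estimated correlation. Without extract rat 4 the median was 0.07. Of 27 glutathione and antioxidant enzymes, 3 rose, 0 fell and 24 did not pass (3 adjusted over the list alone). These included Gsr, the glutathione reductase, which the NRF2 list also holds (1.79-fold, from 9.66 ± 0.14 to 10.50 ± 0.11, SD, n = 7 each). The others were the transferase Gstt1 (1.38-fold) and the glutathione synthetase Gss (1.28-fold). The list's camera call (adjusted p = 0.017, median 0.12) had adjusted p = 0.39 with an estimated correlation, and was lost among genes with a mean of at least 6 or with a mean above the median gene (adjusted p = 0.052 and 0.054).

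**Figure D2:**
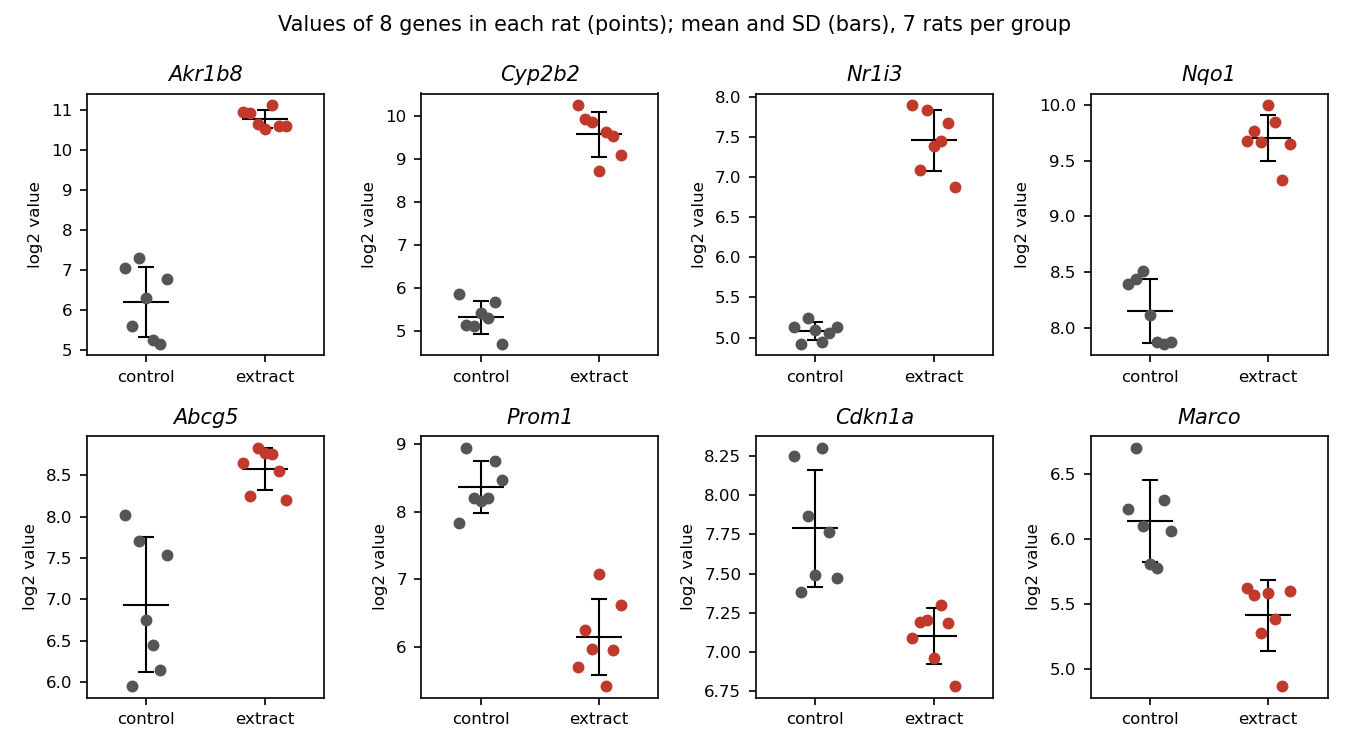
Log2 values (y axis, scaled per panel) of 8 genes in each of 7 control rats (grey) and 7 extract rats (red); bars give the mean and SD. The groups do not overlap in any of the 8 panels, with Akr1b8, Cyp2b2, Nr1i3, Nqo1 and Abcg5 higher and Prom1, Cdkn1a and Marco lower with the extract.

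In the list of bile acid synthesis and transport, 3 of 20 measured genes rose and 17 did not pass (3 rose adjusted over the list alone). Abcg5 and Abcg8, partner transporters that export sterols into bile, rose 3.11-fold (6.93 ± 0.81 to 8.57 ± 0.25, SD, n = 7 each; adjusted p = 0.00164) and 1.90-fold (adjusted p = 0.00397). Nr0b2, the receptor SHP that represses bile acid synthesis, rose 1.72-fold (adjusted p = 0.010). Cyp7a1, an enzyme of bile acid synthesis named here after its value was seen, did not pass, with a positive log2 fold (0.92 ± 0.33 SE, adjusted p = 0.17). Lower bile acid synthesis can therefore not be read from the rise of Nr0b2. In the unequal-variance test per gene only the call of Abcg8 was held, and those of Abcg5 and Nr0b2 were lost (adjusted p = 0.066 and 0.078). The list's median was 0.09, and its camera call (adjusted p = 0.00958) had adjusted p = 0.31 with an estimated correlation. The median was 0.05 without control rat 1 and 0.06 without extract rat 7. Of 20 genes of cholesterol synthesis and uptake, 0 rose and 2 fell (1 rose and 4 fell adjusted over the list alone). These were the mevalonate pathway enzymes Mvd (log2 fold -0.54, adjusted p = 0.022) and Pmvk (-0.45, adjusted p = 0.037), while Dhcr7, which acts at the end of cholesterol synthesis, had a log2 fold of 0.37 (adjusted p = 0.083; 0.049 without extract rat 4, and 0.010 to 0.029 under 3 other settings). The list's median was -0.16, with camera adjusted p = 0.000315, but adjusted p = 0.39 with an estimated correlation. The call of Pmvk was lost without control rat 2, 3 or 5 or extract rat 1, 3, 5, 6 or 7 (adjusted p from 0.052 to 0.082), after median centring (0.071) and after repeated quantile normalization (0.060). Under 1 further limma setting it was lost too. In the unequal-variance test per gene the calls of both Mvd and Pmvk were lost (0.11 and 0.12).

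Genes of fatty acid and triglyceride synthesis changed in both directions: 3 of 26 rose and 1 fell (4 rose and 3 fell adjusted over the list alone), with a camera adjusted p of 0.49. Me1, the malic enzyme that supplies NADPH and that the NRF2 list also holds, rose 2.34-fold (adjusted p = 2.28e-06). Lpin2, a phosphatidate phosphatase, rose 1.31-fold and Dgat1, a triglyceride synthase, 1.21-fold, a call held without control rat 1 or extract rat 6 or 7 and lost without each of the other 11 rats (adjusted p from 0.055 to 0.10) and with an intensity trend (0.082). The calls of Lpin2 and Dgat1 were lost in the unequal-variance test per gene (0.062 and 0.056). Cidec, a lipid droplet protein, fell (log2 fold -0.33, adjusted p = 0.022; 0.052 without extract rat 1). Of 28 PPARA targets and fatty acid oxidation genes, 1 rose, Cyp4a8 (log2 fold 0.44, adjusted p = 0.00219, 1 adjusted over the list alone), with both means below the median probe (3.69 and 4.13). Fabp1 (log2 fold -0.18, adjusted p = 0.10; 0.038 after repeated quantile normalization and 0.037 in the unequal-variance test per gene) and Plin2 (-0.38, adjusted p = 0.16; 0.010 without control rat 1, and 0.013 to 0.024 under 3 other settings) did not pass. That list's camera call (adjusted p = 0.037, median 0.11) had adjusted p = 0.49 with an estimated correlation, and was lost without control rat 1 or 4 or extract rat 2, 3, 5 or 7 (adjusted p from 0.054 to 0.11), after repeated quantile normalization (0.21) and among genes with a mean of at least 6 (0.24). Of 23 genes of gluconeogenesis and glucose handling, 2 rose (4 rose and 1 fell adjusted over the list alone): the glucose transporter Slc2a1 (1.59-fold, adjusted p = 0.000128) and the coactivator Ppargc1a (1.68-fold, adjusted p = 0.000624). Igfbp1 did not pass (log2 fold 0.69, adjusted p = 0.067) but did without control rat 4 or extract rat 4 or 5 (0.049, 0.025 and 0.033) and under 6 other settings (0.013 to 0.047), median centring and array weights among them. The list's camera call (adjusted p = 0.022, median 0.08) had adjusted p = 0.59 with an estimated correlation, and was lost without control rat 1 (median 0.02, adjusted p = 0.26), extract rat 1 (0.07, adjusted p = 0.062) or extract rat 7 (0.08, adjusted p = 0.072). Its median was 0.12 without control rat 7 and 0.05 without extract rat 3. In lipoprotein and lipid handling limma called 0 of 22 genes (0 adjusted over the list alone; 6 had an unadjusted p under 0.05). Its smallest p was that of Cd36, a fatty acid transporter (log2 fold 0.48, adjusted p = 0.077; 0.013 without control rat 1, and 0.019 to 0.037 under 3 other settings). In the mitochondrial respiratory chain limma called 0 of 32 (0 adjusted over the list alone; 5 had an unadjusted p under 0.05), with Ndufs1 first (0.33, adjusted p = 0.089; 0.041 without control rat 2, and 0.010 and 0.040 under 2 other settings). The camera adjusted p of these lists was 0.49 and 0.38, the latter 0.043 without control rat 1. The unequal-variance test per gene called 0 genes in both lists.

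Of 18 genes of the p53 and DNA damage list, 3 fell and 1 rose (3 and 1 adjusted over the list alone). Those that fell were Phlda3 (log2 fold -0.77, adjusted p = 0.00114), the cell cycle inhibitor Cdkn1a (7.79 ± 0.37 to 7.10 ± 0.18, SD, n = 7 each; log2 fold -0.69, adjusted p = 0.00811) and Ccng1 (-0.34, adjusted p = 0.00899). Gadd45b, a stress-inducible gene that the CAR and PXR list also holds, rose 1.83-fold (adjusted p = 0.016). The calls of Cdkn1a and Gadd45b were lost in the unequal-variance test per gene (adjusted p = 0.082 and 0.13). The camera adjusted p of the list was 0.49. Among 19 immediate early genes, Myc, a growth-promoting transcription factor, rose 1.92-fold in all 7 extract rats above the controls (adjusted p = 0.00393) and 18 did not pass (2 rose adjusted over the list alone). limma called 0 of 27 cell cycle genes (0 adjusted over the list alone; 2 had an unadjusted p under 0.05), with Pcna first (log2 fold 0.31, adjusted p = 0.18). In the unfolded protein and integrated stress response, 1 of 23 genes rose, Trib3, a pseudokinase that the NRF2 list also holds (1.61-fold, adjusted p = 0.00595; 1 rose and 1 fell adjusted over the list alone). Of 16 heat shock genes, Hspd1, a mitochondrial chaperonin, rose (log2 fold 0.36, adjusted p = 0.048) and Hspa4l fell (-0.54, adjusted p = 0.042; 1 and 1 adjusted over the list alone). The call of Hspd1 was held without control rat 2 or extract rat 4 or 5 and lost without each of the other 11 rats (adjusted p from 0.056 to 0.11) and after repeated quantile normalization (0.077). That of Hspa4l was held without control rat 1, 4 or 7 or extract rat 2 and lost without each of the other 10 (0.060 to 0.089). Each call was also lost under 1 further limma setting (0.052 for Hspd1 and 0.051 for Hspa4l). Both calls were lost in the unequal-variance test per gene (0.12 and 0.14). limma called 0 of 16 circadian clock genes (0 adjusted over the list alone; 3 had an unadjusted p under 0.05), with Per2 first (log2 fold -0.72, adjusted p = 0.082; 0.013 without control rat 1, and 0.014 to 0.028 under 3 other settings). It called 0 of 22 growth hormone and sex-biased genes (2 rose and 1 fell adjusted over the list alone; 8 had an unadjusted p under 0.05), with Cyp3a2 first (0.74, adjusted p = 0.068; 0.022 without extract rat 4, and 0.019 to 0.042 under 4 other settings). Both Cyp3a2 means (3.46 in control and 4.20 in extract rats) lay below 5.10, the median of all probes in controls. Extract rats 3 and 5 stood highest (5.21 and 4.92), against at most 4.11 in the other extract rats. The unequal-variance test per gene called 0 genes in the cell cycle, clock and growth hormone lists. The camera adjusted p was 0.41 for immediate early genes, 0.98 for the cell cycle, 0.49 for the unfolded protein list, 0.97 for heat shock, 0.38 for the clock and 0.49 for growth hormone and sex-biased genes.

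Markers of Kupffer cells and other macrophages were lower with the extract, while 0 of 20 hepatocyte markers passed. All 17 measured macrophage markers had a negative log2 fold, with a median of -0.26. Over all genes 2 fell, and 14 fell adjusted over the list alone. The 2 were Marco, a scavenger receptor (6.14 ± 0.32 to 5.41 ± 0.27, SD, n = 7 each; log2 fold -0.73, adjusted p = 0.00586), and Vsig4, a complement receptor (-0.51, adjusted p = 0.024; 0.054 and 0.062 without extract rat 1 or 2, and 0.097 in the unequal-variance test per gene). The Kupffer cell lectin Clec4f had a log2 fold of -0.26 (adjusted p = 0.052; 0.049 without extract rat 7, and 0.027 to 0.050 under 3 other settings), with all 7 extract rats below the controls. Camera gave an adjusted p of 1.46e-10, but adjusted p = 0.085 with an estimated correlation. fry, which tests whether a list's genes move one way on balance, gave an adjusted p of 0.00527. The mean over the 17 markers was lower by 0.29 in the extract group (SD 0.12 in control and 0.13 in extract rats, n = 7 each; exact two-sided permutation p = 0.000583, and 0.00524 adjusted over 9 scores), below every control in 7 of 7 rats. That test was added after the data had been seen, and 0.000583 is the smallest p it can give for 7 against 7 arrays. limma called 0 of 20 hepatocyte markers, as did the unequal-variance test per gene (1 rose adjusted over the list alone; 3 had an unadjusted p under 0.05; camera adjusted p = 0.97). Otc had the smallest p (log2 fold 0.28, adjusted p = 0.058; 0.033, 0.040 and 0.042 without control rat 5, control rat 6 or extract rat 1, and 0.034 and 0.045 under 2 other settings).

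Markers of other cell types of the liver had smaller differences. Of 22 stellate cell and fibroblast markers, Pdgfra (log2 fold -0.38, adjusted p = 0.037) and Pdgfrb (-0.37, adjusted p = 0.042), receptors for platelet-derived growth factor, fell (3 fell adjusted over the list alone). The call of Pdgfra was lost without control rat 1, 2, 6 or 7 or extract rat 1, 2, 3 or 5 (adjusted p from 0.052 to 0.088), after median centring (0.052) and after repeated quantile normalization (0.055). Under 1 further limma setting this call was lost too (0.065). That of Pdgfrb was held without control rat 1 or 4 or extract rat 6, and lost without each of the other 11 rats (0.051 to 0.087) and with an intensity trend (0.054). Lrat, which stores retinoid in stellate cells, had a log2 fold of -0.48 (adjusted p = 0.059; 0.047 and 0.014 without extract rat 1 or 6, and 0.030 to 0.044 under 3 other settings). The list's camera call (adjusted p = 0.00492, median -0.16) had adjusted p = 0.39 with an estimated correlation, and the median was -0.10 without control rat 1. limma called 0 of 15 liver endothelial markers (0 adjusted over the list alone; 3 had an unadjusted p under 0.05), with Erg (-0.34), Pecam1 (-0.24) and Kdr (-0.23) first. The camera call of that list (adjusted p = 0.00143, median -0.14) had adjusted p = 0.49 with an estimated correlation, and the median was -0.10 without extract rat 2. It called 0 of 23 lymphocyte markers (0 adjusted over the list alone; 3 had an unadjusted p under 0.05; Klrb1a -0.27, Cd4 -0.19 and Klrd1 -0.34 first). Their camera adjusted p of 0.037 (median -0.06) was adjusted p = 0.39 with an estimated correlation, and was lost without control rat 1 or 4 or extract rat 1, 2 or 5 (0.057 to 0.23). The median was -0.04 without control rat 5 and -0.09 without extract rat 4. Of 19 neutrophil and blood cell markers limma called 0 (0 adjusted over the list alone; 2 had an unadjusted p under 0.05; Csf3r -0.37, Mmp9 -0.19 and Hbb -0.29 first). Their camera adjusted p of 0.039 (median -0.14) was adjusted p = 0.49 with an estimated correlation, and was lost without control rat 1, 4 or 6 or extract rat 2, 3, 6 or 7 (0.057 to 0.23). The median was -0.09 without control rat 1 and -0.08 without extract rat 7. The unequal-variance test per gene called 0 genes in these 4 lists, so the calls of Pdgfra and Pdgfrb were lost (0.12 in both). fry, which called the macrophage list, gave adjusted p = 0.10 for stellate cell, 0.21 for endothelial, 0.19 for lymphocyte and 0.24 for neutrophil and blood cell markers.

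Of 15 cholangiocyte markers, Prom1 fell and 14 did not pass (1 fell adjusted over the list alone). Because of Prom1 the mean of this list was -0.08 while its median was 0.13 and camera's direction was upward (adjusted p = 0.49). Without extract rat 4 the median was 0.05. The mean, median and camera direction also differed in sign for the hepatocyte and cell cycle lists, whose camera adjusted p were 0.97 and 0.98. Of 15 adipose tissue markers, Cidec fell and 14 did not pass (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.12). limma and the unequal-variance test per gene called 0 of 19 pancreas markers (0 adjusted over the list alone; 2 had an unadjusted p under 0.05; Pnlip first, log2 fold 0.18). Their camera adjusted p of 0.060 fell below 0.05 without control rat 1 or 3 or extract rat 2 or 3 (0.026, 0.040, 0.032 and 0.020).

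Inflammation and interferon genes included a few that fell. Of 28 acute phase and inflammation genes, 2 fell and 0 rose (5 fell adjusted over the list alone). These were the cytokine Il1b (7.40 ± 0.34 to 6.65 ± 0.30, SD, n = 7 each; log2 fold -0.74, adjusted p = 0.00882) and the acute phase protein Orm1 (-0.71, adjusted p = 0.020). The call of Orm1 was lost without control rat 3 or extract rat 2 or 3 (adjusted p = 0.051, 0.052 and 0.0505). In the unequal-variance test per gene the calls of Il1b and Orm1 were both lost (0.058 and 0.099). The list's camera adjusted p was 0.25. Of 25 interferon response genes, 2 fell (2 adjusted over the list alone): the immunoproteasome subunit Psmb8 (log2 fold -0.41, adjusted p = 0.010), lower in all 7 extract rats than in any control, and the ubiquitin-like modifier Isg15 (-0.96, adjusted p = 0.029), whose call was lost without control rat 3, 4, 6 or 7 or extract rat 1, 2, 4 or 7 (adjusted p from 0.052 to 0.071) and with array weights (0.067). The calls of Psmb8 and Isg15 were both lost in the unequal-variance test per gene (0.066 and 0.14). That of Isg15 was also lost under 1 further limma setting (0.061). Irf1 did not pass (-0.43, adjusted p = 0.16; 0.013 without control rat 1, and 0.022 to 0.044 under 3 other settings). The list's camera call (adjusted p = 0.00035, median -0.19) had adjusted p = 0.39 with an estimated correlation, and fry gave adjusted p = 0.21. Without extract rat 4 the median was -0.06: the mean over the list's genes was -0.84 in that rat and -0.54 to 0.12 in the other 6 extract rats, relative to the control mean. In the same rats the macrophage score differed by -0.29.

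**Figure D3:**
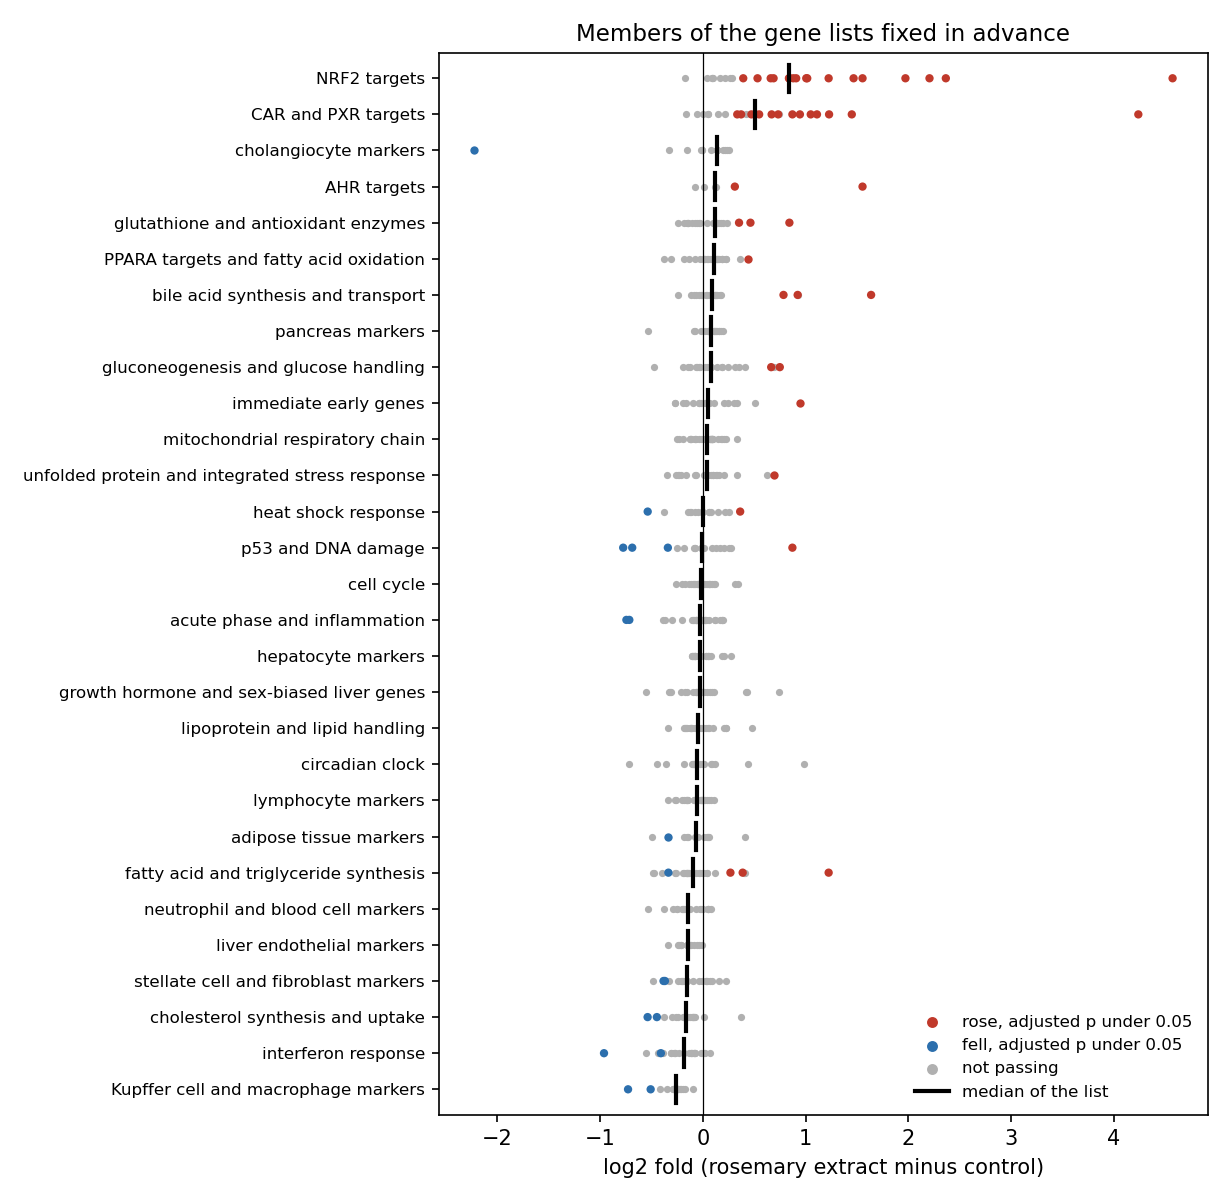
Each row is 1 of 29 gene lists and each point a measured member at its log2 fold, extract minus control (x axis); red members rose and blue members fell at an adjusted p of 0.05 over all genes, grey ones did not pass, and black bars are list medians. The NRF2 and the CAR and PXR lists stand to the right at medians of 0.84 and 0.51, and the macrophage list lies farthest to the left at -0.26.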

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

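Single rats stood apart from the other 6 of their group in 8 of the 146 groups examined (73 named genes in 2 groups), where chance gives about 7.3. The log2 value of Gstp1 was 11.85 in extract rat 7, against 12.25 to 12.39 in the other extract rats. Ky was 7.71 in extract rat 7, against 6.54 to 7.04. Gstt1 was 10.08 in control rat 1, against 10.43 to 10.68 in the other controls. Ppargc1a was 6.72 in extract rat 4, against 6.93 to 7.03. Vsig4 was 10.83 in control rat 1, against 10.14 to 10.37, and Erg was 7.86 in control rat 7, against 7.13 to 7.44. Klrb1a was 5.41 in control rat 7, against 4.59 to 4.92. Pnlip was 4.80 in extract rat 4, against 4.26 to 4.43.

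Outside the genes tested, 13905 probes had no single gene name here. Of these, 47 differed between extract and control rats at an adjusted p of 0.05 in limma's test, fitted and adjusted over these probes alone, 32 higher and 15 lower with the extract.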

How the results depend on the processing

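Fits without the 2 arrays of lowest weight and with the largest component as a covariate were chosen after the data had been seen. Of 457 genes called, 0 were called in the opposite direction under any alternative fit compared, and the lists of NRF2 and of CAR and PXR targets were called upward under every alternative run. The number of genes differing was 694 with array weights (262 lower), 967 with the component (549 higher, 418 lower), 227 in the unequal-variance test per gene (171 higher, 56 lower) and 719 at an adjusted p of 0.1 (291 lower). The unequal-variance test also drops limma's moderated variance, so its count of 227 does not measure unequal spread alone. The component's fit called all 457 genes among its 967. With every probe of the table, 3505 had an unadjusted p under 0.05, which follows from testing 29215 probes. The number of lists was 9 among genes with a mean of at least 6 and 9 among genes with at least the mean of the median gene, 2 with an estimated correlation and 7 by fry. The cause of the other differences was not tested. By fry the adjusted p was 7.34e-08 for NRF2 targets, 1.31e-05 for CAR and PXR targets, 0.000183 for AHR targets, 0.00527 for macrophage markers, 0.0325 for bile acid genes and 0.0498 for antioxidant enzymes. It was 0.125 for cholesterol, 0.263 for gluconeogenesis and 0.206 for PPARA genes, and 0.0159 for adipose tissue markers, which camera did not call. The AHR list has only 6 measured genes, shares Nqo1 (log2 fold 1.55) with the NRF2 list, and was not tested without it. Without the 2 arrays of lowest weight (control rat 1 and extract rat 4), 575 genes were called, 402 of them among the 457. Other alternatives stayed within 1.5 times of the main counts.

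Leaving out 1 rat gave 326 to 621 genes differing, 209 to 329 higher and 116 to 292 lower (292 without control rat 1), 1824 to 2545 at an unadjusted p under 0.05 and 11 to 15 lists. At the preset correlation camera called the macrophage list without each of the 14 rats, with a median from -0.28 to -0.23; with an estimated correlation it did not call it over all rats (adjusted p = 0.085). The named genes lost their call in 77 of these fits and gained one in 16; those near the threshold are named with their results. Csf3r, Fabp1 and Klrd1, not called over all rats, were each called under 1 other limma fit (0.049, 0.038 and 0.023). Rats of the groups share only numbers: the deviations of same-numbered rats correlated from -0.46 to 0.28, and 4 of 14 arrays correlated best with their own number. With the number as a replicate block 364 genes were called, 334 of them among the 457; 5 named genes were then not called and 1 more was.

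Signal over background limits genes whose values lie near the low end, such as Cyp1a1, Cyp3a2 and Cyp4a8. It may also limit Nr1i3 and Cyp2b2 in controls, and Slc34a2, Cyfip2 and Marco in extract rats. The number of arrays limits what can be called: changes of 0.5 on the log2 scale were recovered in 86.6% of simulated genes. Those genes were independent and equally spread in both groups, so recovery in the real data may be lower. Larger changes of variable genes, such as Igfbp1 (0.69), did not pass in the main fit.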

Other observations

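The groups of genes in the first 2 paragraphs and the tests of the macrophage, pericentral and NRF2 patterns were chosen after the results had been seen; the counts over other splits were planned. Gene families sharing a symbol stem were compared with all other genes by one-sided Fisher's exact tests (253 families of at least 8 measured genes, 506 tests, Benjamini-Hochberg adjusted). Carboxylesterases stood first, with 8 of 10 Ces genes higher with the extract (adjusted p = 5.1e-10). Of the mu-class glutathione transferases 5 of 8 Gstm genes rose (adjusted p = 4.16e-05), of the glucuronosyltransferases 4 of 8 Ugt genes (0.00114), of the aldo-keto reductases 5 of 16 Akr genes (0.00114) and of the cytochromes P450 10 of 69 (0.000177), while Cyp17a1 and Cyp4b1 fell. Among transporters, 18 of 315 Slc genes rose (0.00555), while Slc34a2 and Slc43a2 fell and the rest did not pass. Of 8 Abcb genes 3 rose (0.0297). The Abcg family, with 2 of 8 higher and Abcg2 lower, and the Abcc family, with 2 of 10 higher, did not pass this test (0.434 and 0.628). Fewer genes fell together: 4 of 35 RT1 genes of the major histocompatibility complex, RT1-DMa, RT1-DMb, RT1-N2 and RT1-N3 (adjusted p = 0.0425). Neighbouring copies in these families are alike in sequence, so their members may not be independent. Over all genes, 290 of 14506 rose and 167 fell. All other genes served as background, among them 1052 Or genes of which 0 rose and 0 fell. No background limited to genes expressed in liver was used, so these adjusted p may be too small.

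Of 18 measured genes of serine, proline and one-carbon synthesis, 7 rose and 1 fell, with a median log2 fold of 0.28. This group and the 2 after it were chosen once the results had been seen, so the counts only describe them and the camera values computed for them are not used. Those that rose include Phgdh (0.54) and Psat1 (0.63), enzymes of serine synthesis, Pycr1 (0.64), of proline synthesis, and the folate enzyme Aldh1l1 (0.65). Gldc, of glycine cleavage, had a log2 fold of -0.76. Of 19 antigen presentation genes, 0 rose and 5 fell, while the median was -0.02. RT1-DMa (-0.66) and RT1-DMb (-0.60) fell, whereas Cd74 (-0.0047) did not pass. Of 19 periportal hepatocyte genes 1 fell, Hsd17b13 (-0.42).

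Chance was weighed by drawing 100 splits of the 14 arrays, 7 against 7, the real one included. For genes at an adjusted p of 0.05, 1 of 100 splits reached the real count of 457, and the highest of the others was 343. For genes at an unadjusted p under 0.05, 3 of 100 splits reached 2154, the highest of the others being 3169. For gene lists, 3 of 100 splits reached 14, the highest of the others also being 14. The share of splits lay below 0.05 for all 3 counts. Chance is argued against most clearly for the count of 457, which no other split reached. For the unadjusted count and the list count, a share of 3 in 100 drawn splits is imprecise. Chance is therefore not firmly excluded for them, and splits that mix the groups also reached 14 lists. The split with 3169 genes correlated at 0.79 with the largest principal component of the genes outside the lists, a structure of the arrays that holds 26.0% of their variance and in which control rat 1 and extract rat 4 stand lowest. The real split correlated with it at 0.06. The median over the other splits was 7 lists, so camera at the preset correlation also called lists in splits that mix the groups.

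All 17 macrophage markers had a negative log2 fold, of which 2 passed over all genes and 15 did not, and camera's adjusted p was 0.085 with an estimated correlation. The macrophage score minus the mean of the endothelial, stellate and lymphocyte scores differed by -0.18, extract minus control. Its exact two-sided permutation p was 0.00524 (0.0236 adjusted over 9 scores), with 6 of 7 extract rats below all controls. The macrophage markers thus fell more than the mean of those 3 lists. A smaller share of all non-hepatocyte cells alike stays open. Markers near background, such as Klrb1a (4.86 in controls), can move less for the same loss of cells. Variation between arrays that is unrelated to the groups is argued against by the exact permutation p of the score, 0.000583 (0.00524 adjusted over 9 scores), with 7 of 7 extract rats below all controls. Differences in handling that follow the groups stay open, since no batch was used here. Fewer macrophages with unchanged expression per cell remains open: 0 of 17 markers differed from the list's median at an adjusted p of 0.05, Marco coming closest (0.0614). A lower expression of these genes per macrophage, as an effect of the extract, was not separated from it and may also hold.

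Rhbg (log2 fold 1.84), Nr1i3 and Aldh1a1 rose, and all 3 are genes of hepatocytes around the central vein. Over all 16 measured pericentral genes, these 3 included, the median log2 fold was 0.085 (SD 0.88 between genes), against 1.45 for the smallest of the 3. The 3 are the highest of the 16, so this median could not have reached them and decides nothing. The other 13 had a median of -0.11 and a highest value of 0.92, and 1, Oat (-0.78), fell. That each of the 13 lies below the 3 was fixed by choosing the highest, so their highest value decides nothing. Their median of -0.11 was not fixed by that choice. It argues against a rise of the whole pericentral programme by about as much. A smaller rise of some members stays open.

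The 18 NRF2 targets that rose had a larger SD among controls than among extract rats in 13 cases, where 54.4% of all genes did. Whether 13 of 18 exceeds that share was not tested. Compression of bright signals in the extract arrays cannot be told apart from a difference between the rats. The controls' SDs were 1.39 times those of genes equally bright in controls (above 99.9% of 10000 random lists). This lies between the bounds of 1.2 and 1.5, which were set after the results had been seen. A control SD does not measure compression in the extract arrays, so the ratio cannot decide the question. Those of the extract rats were 1.29 times those of genes equally bright in extract rats. For the 272 other genes that rose the ratios were 0.93 in controls and 0.95 in extract rats, though genes that pass the test are chosen in part for a small SD.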
